A study of Homo sapiens with 4 samples.

How the data were processed

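RNA from 2 lysates of doxycycline-induced Flp-In T-REx HEK293 cells and from 2 anti-FLAG immunoprecipitates of FlagHA-tagged FMRP was measured on Affymetrix human expression arrays, 1 array per sample. Per the labels' protocols, doxycycline was used at 1 µg/ml for 16 h, IPs were washed at 300 mM KCl, and 2 µg of RNA was labelled with biotin for each array. The deposited values are log2 probe set signals, a scale read from their range and from array medians of 4.68 to 4.71. The background correction, summary method and normalization that the authors used before deposition, and any scan date or batch, are not given in the sources used here. The near-equal distributions show that the arrays were scaled to each other, so a change is relative to the other probe sets. The table holds no detection calls, so low values have no known floor, and the arrays' number limits the precision.

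Of 54675 probe sets, 62 were controls, 41091 had 1 gene symbol, 1801 had several and 11721 had none in the platform annotation. Of those with 1 symbol, 41037 were matched through the Entrez number to the GRCh38.p14 gene table, which was used for names, chromosome and gene class only. Probe sets with several symbols or none were left out of gene-level tests, and list members with no probe set of their own were not analysed here. Probe sets with a mean over the 4 arrays of at least 4.70, the median of all probe sets, were kept, and each gene was represented by its probe set with the highest mean, which gave 13157 genes. No genomic coordinates are printed. The result of 1 other gene family is not reported here.

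IP minus lysate was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate, 2 residual degrees of freedom and 5.51 prior degrees of freedom), with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over the 25 lists, with an estimated correlation and fry beside it. No list call held with an estimated correlation, a setting in which camera uses only the 2 residual degrees of freedom. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3.

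The design, the 25 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. A naming table that links symbols of mitochondrially encoded genes and of NDUFA4 to the annotation was added afterwards. The rule names FMR1, FXR1 and FXR2, then the 12 genes with the largest rise and the 12 with the largest fall among called genes whose IP arrays both lie on the same side of both lysate arrays, and per list up to 3 members, 2 with the largest change in the direction of the list median and 1 in the other direction. Of the genes named by the rule, FMR1, NABP1, COX3, SDHA, RPL3, HSP90B1, EIF3B, PSME3, PFKL and TPI1 were represented by probe sets that can cross-hybridize. Other genes are named only where the text says so. Alternatives covered normalization, the filter, the choice of probe set, the replicate number as a block, the spread estimate, the threshold and leaving out each array. Groups by transcript length or sequence element were planned and not run, because the gene table gives genomic spans and no transcripts.

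The fit was tested on simulated data with 200 changed genes among 13157. It recovered 6% of genes changed by 0.5 on the log2 scale, 84% at 1, and 100% at 2 and at 3, with 6 false calls beside 145 true ones. In the data far more genes were called (8401), so a larger unadjusted p passes and these shares do not carry over. Changes under 0.5 also passed there, such as that of DAP3 (0.32). In 100 simulated sets without change, 2.88% of list tests gave p under 0.05.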

Results

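RNA recovered by immunoprecipitation of the fragile X protein FMRP was compared with total RNA of the starting lysate. FMRP, the product of FMR1, is an RNA-binding protein whose loss causes fragile X syndrome. The cells were a Flp-In T-REx HEK293 line, a human embryonic kidney line in which a stably integrated transgene is switched on by doxycycline, and here the transgene encoded FMRP with a FLAG and HA tag. After 16 h of induction, 2 lysate RNA samples were set aside, and 2 RNA samples were recovered by immunoprecipitation (IP) with an anti-FLAG antibody. Each of the 4 samples was hybridized to its own Affymetrix human expression array with 54675 probe sets. Across the 13157 genes tested, Pearson's r was 0.993 between the lysate arrays, 0.992 between the IP arrays, and 0.873 to 0.903 between a lysate and an IP array. These r values are across genes, which are not independent replicates. The arrays number 2 per group, and their number limits the precision. The labels do not say that replicates came from separate cultures, or which lysate and IP sample share a culture. The gene p-values therefore measure only the spread between these samples, pooled in part over genes, and this spread may be technical. The camera p-values at the preset correlation judge list members against the spread among genes, not between samples.

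The first question was where the mRNAs of FMRP and its autosomal paralogs lay. FXR2 was 3.97-fold higher in the IP than in the lysate, at 10.85 ± 0.02 against 8.86 ± 0.13 (mean log2 signal ± SD, n = 2 each; limma, adjusted p = 3.4e-05), and its other probe set changed by 1.79. FMR1 fell by 0.42 on the log2 scale, from 9.58 ± 0.10 in the lysate to 9.16 ± 0.18 in the IP (adjusted p = 0.0261), and its other probe set changed by -0.69. The FMR1 change did not pass without lysate replicate 1 (-0.35), lysate replicate 2 (-0.48) or IP replicate 2 (-0.29). FXR1 stood at 9.48 ± 0.10 and 9.43 ± 0.03, a change of -0.05 with a 95% interval of -0.33 to 0.23 (adjusted p = 0.729), and its other probe sets changed by 0.01, 0.03, 0.06 and 0.83. The FMR1 probe set belongs to a class that can cross-hybridize, and whether it detects the transgene mRNA as well as the endogenous mRNA was not analysed here.

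The main comparison asked which mRNAs were over- or under-represented in the FMRP IP. At an adjusted p of at most 0.05, 4611 genes were higher in the IP and 3790 were lower, together 63.9% of the genes tested, while 4756 did not pass. With a change of at least 2-fold there were 1639 higher and 1683 lower genes, and at least 4-fold 101 higher and 255 lower genes. The IP arrays lay on the same side of both lysate arrays for 82.3% of genes, where chance gives 33.3%. The median change over all genes was 0.08 with an interquartile range of -0.48 to 0.61. All changes are relative to the scale of the deposited values: with each array centred on the median of its hybridization controls, which lay 0.53 higher on the IP arrays, the median of all genes moved to -0.45 and the split became 1634 higher against 6442 lower, or 20.2% of calls higher in place of 54.9%. No mock IP is among these samples, so RNA recovered independently of FMRP was not measured.

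The largest rise was that of HINT3, which was 8.54-fold higher in the IP (log2 change 3.09 ± 0.15 SE, n = 2 against 2, limma adjusted p = 3.4e-05). ZNF91, a KRAB zinc finger gene, was 8.27-fold higher and EPPK1, encoding the cytoskeletal linker epiplakin, was 7.48-fold higher. ZBED1 was 7.22-fold higher and DDX42, a DEAD-box RNA helicase gene, 6.57-fold higher. FBN1, encoding the microfibril protein fibrillin, rose 6.47-fold and JPH3, encoding a junctophilin that links plasma membrane and endoplasmic reticulum, rose 6.24-fold. MTOR, the nutrient-sensing kinase gene, rose 6.22-fold and WDR59, encoding a component of the GATOR complex upstream of it, rose 6.07-fold. The noncoding RNA CCDST, the secretory granule gene SCG3 and the receptor phosphatase gene PTPRB completed the 12 largest rises, from lysate means of 4.22, 3.55 and 3.76 to IP means of 7.14, 6.41 and 6.47. These lysate means lie below the array medians of 4.68 to 4.71, where no floor is known, so no fold is given. All 12 passed at an adjusted p of 3.5e-05 or lower. Probe sets of the same gene did not always move together: other HINT3 probe sets changed by -0.58 and 1.73, other JPH3 probe sets by 0.53 and 1.18, and the other WDR59 probe set by 0.65.

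The largest fall was that of NDUFA1, a subunit of respiratory complex I, whose signal was 9.50-fold higher in the lysate than in the IP (11.83 ± 0.03 against 8.58 ± 0.53, mean log2 ± SD, n = 2 each; limma adjusted p = 3.5e-05). COX8A, a cytochrome c oxidase subunit, was 7.74-fold higher in the lysate, and the mitochondrially encoded ATP6 was 7.81-fold higher. MOCS2, needed for molybdenum cofactor synthesis, fell by 3.19 on the log2 scale. TMEM167A changed by -3.12, TMEM230 by -2.91, the orphan receptor gene GPR160 by -3.01 and the embigin gene EMB by -2.92. OST4, encoding a very small subunit of oligosaccharyltransferase, was 7.81-fold higher in the lysate. NABP1, SLC25A40 and the pseudogene SEPTIN7P13 fell from lysate means of 7.20, 6.37 and 6.87 to IP means of 4.03, 3.34 and 3.91 below the array medians, and no fold is given. The IP arrays differed for some of these genes: IP replicates 1 and 2 stood at 4.03 and 2.65 for SLC25A40 and at 4.61 and 3.44 for NABP1, and the change of ATP6 was -2.32 without IP replicate 2 and -3.61 without IP replicate 1. The probe set of NABP1 can cross-hybridize. All 12 passed at an adjusted p of 2.6e-04 or lower. The values of these 12 genes and of the 12 that rose are shown per array in the plot of single genes.

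**Figure D1:**
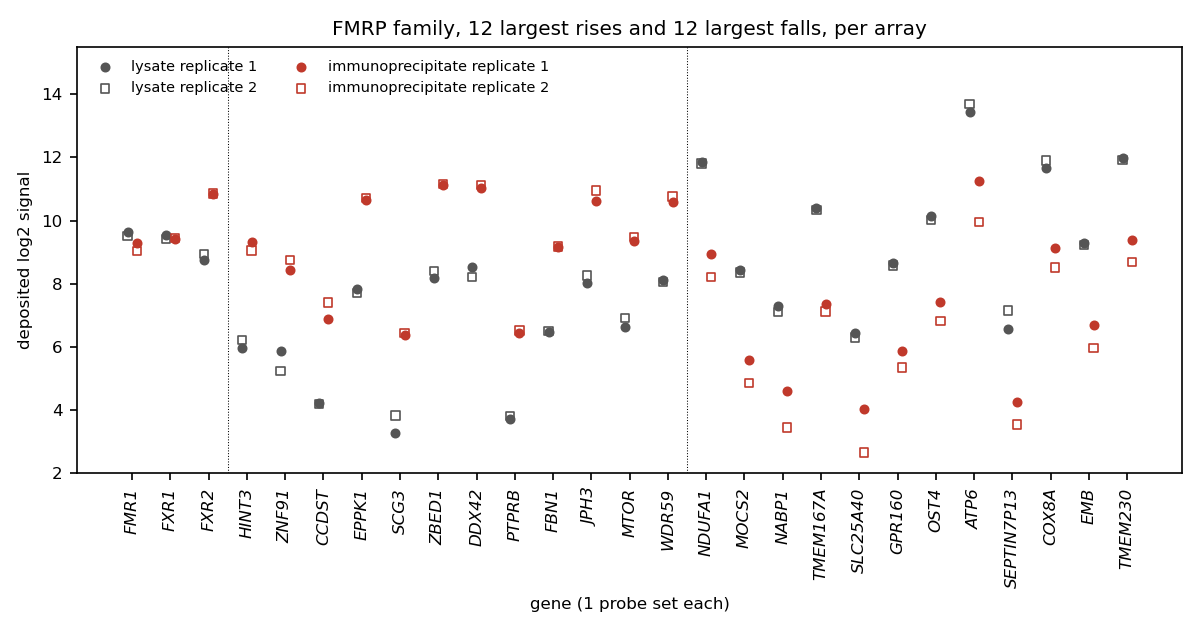
Deposited log2 signal (vertical axis) of FMR1, FXR1, FXR2, the 12 genes with the largest rise and the 12 with the largest fall, for each lysate array (grey) and IP array (red); circles are replicate 1 and squares replicate 2, and dotted lines part the 3 sets. For FXR2 both IP arrays (10.83 and 10.86) lie above both lysate arrays (8.76 and 8.95), and for NDUFA1 both IP arrays (8.95 and 8.21) lie below both lysate arrays (11.84 and 11.81).

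Genes for cell surface and extracellular matrix proteins rose together in the IP. Of 56 measured, 50 were higher, 1 was lower and 5 did not pass; adjusted over the list alone, 51 were higher and 1 lower. Their median change was 1.31 (camera adjusted p = 1.7e-11; adjusted p = 0.273 with an estimated correlation). FBN1 changed by 2.69 and LAMA1, encoding a laminin chain, by 2.10, while the integrin gene ITGB8 was the lower gene, from a lysate mean of 5.26 to IP levels of 4.68 and 4.06 (mean 4.37) near the low end of the arrays. With the mean of each gene's probe sets 3 of these genes were lower. Of 40 genes for cytoskeletal scaffolds and motors, 35 were higher and 1 lower, with the same counts adjusted over the list alone and a median of 1.06 (camera adjusted p = 3.5e-08; adjusted p = 0.257 with an estimated correlation). SPTAN1, encoding a spectrin chain, changed by 2.32, with other probe sets at 2.23 and -0.58, and the talin gene TLN1 by 2.44, with its other probe set at -0.67; the dynein light intermediate chain gene DYNC1LI1 was lower at -0.63, with its other probe set at -1.72. With hybridization control centring the cell surface list had 37 higher and 3 lower genes and a median of 0.78, and the cytoskeletal list 22 and 3 with a median of 0.53.

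Chromatin regulator genes were mostly higher in the IP. Of 56, 44 were higher and 4 lower, over all genes and adjusted over the list alone, with a median of 0.93 (camera adjusted p = 5.8e-07; adjusted p = 0.273 with an estimated correlation). The remodeller genes CHD4 and CHD8 rose 4.48-fold and 3.73-fold. The lower genes numbered 2 without lysate replicate 1, without IP replicate 2 or with the mean of each gene's probe sets. The 4 lower genes were BRWD1 (-1.56, other probe sets -0.59 and -0.96), BRWD3 (-0.95), CHD1 (-0.55) and CHD9 (-0.43), the last 3 named after their values were seen. Of 32 genes for large E3 ubiquitin ligases, 22 were higher and 3 lower, or 22 and 4 adjusted over the list alone, with a median of 0.60 (camera adjusted p = 0.00262; adjusted p = 0.296 with an estimated correlation); HECTD4 changed by 2.09, UBE2O by 2.01, with its other probe set at 0.26, and HECTD2 by -1.36. Among the 12 E3 ligase genes whose 2 or more probe sets share a sign, an alternative chosen after seeing the data, the median was 0.90. Of 35 genes for centrosomal, Golgi and other coiled-coil proteins, 18 were higher and 2 lower, also adjusted over the list alone, with a median of 0.61 (camera adjusted p = 0.00266; adjusted p = 0.639 with an estimated correlation); TPR changed by 1.65 and SMC2 by 1.61, and EEA1 by -0.66. EEA1 did not pass without lysate replicate 1 (-0.35) or without IP replicate 2 (-0.46). No coiled-coil gene was lower without lysate replicate 1 or without IP replicate 2, and the median was 0.28 without lysate replicate 2. With hybridization control centring the counts were 24 higher and 7 lower for chromatin genes (median 0.40), 10 and 8 for E3 ligase genes (median 0.07) and 7 and 6 for coiled-coil genes (median 0.08).

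Genes linked to autism and intellectual disability, and mRNAs described earlier as FMRP ligands, were also higher on balance. Of 46 autism and intellectual disability genes, 29 were higher and 6 lower, or 30 and 7 adjusted over the list alone, with a median of 0.78 (camera adjusted p = 3.8e-04; adjusted p = 0.273 with an estimated correlation). The lower genes numbered 3 without lysate replicate 1, 4 without lysate replicate 2 or IP replicate 1, and 2 without IP replicate 2. ANK2, encoding an ankyrin, rose 4.29-fold, SHANK3, a postsynaptic scaffold gene, rose 4.17-fold, with its other probe set at 0.91, and PHF6 changed by -0.64. Of 30 earlier described ligand mRNAs, 15 were higher and 4 lower, also adjusted over the list alone, with a median of 0.39 (camera adjusted p = 0.0257; adjusted p = 0.484 with an estimated correlation); 2 were lower without lysate replicate 2, and the median was 0.82 in the 14 whose 2 or more probe sets share a sign. With hybridization control centring the ligand median turned to -0.14, with 9 higher and 8 lower, and the autism and intellectual disability list had 14 higher and 10 lower with a median of 0.25. MTOR changed by 2.64, and the glutamate receptor gene GRM5 by -0.81, which did not pass without lysate replicate 2 (-0.70) and was -0.52 without IP replicate 1; DLG4 (-0.74), SOD1 (-0.64) and FMR1 (-0.42) were the other lower ligand mRNAs, FMR1 not passing without lysate replicate 1 (-0.35), lysate replicate 2 (-0.48) or IP replicate 2 (-0.29), DLG4 and SOD1 being named after their values were seen. The lists share genes, among them SHANK3, MTOR, ANK2 and CHD8, and are not independent.

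**Figure D2:**
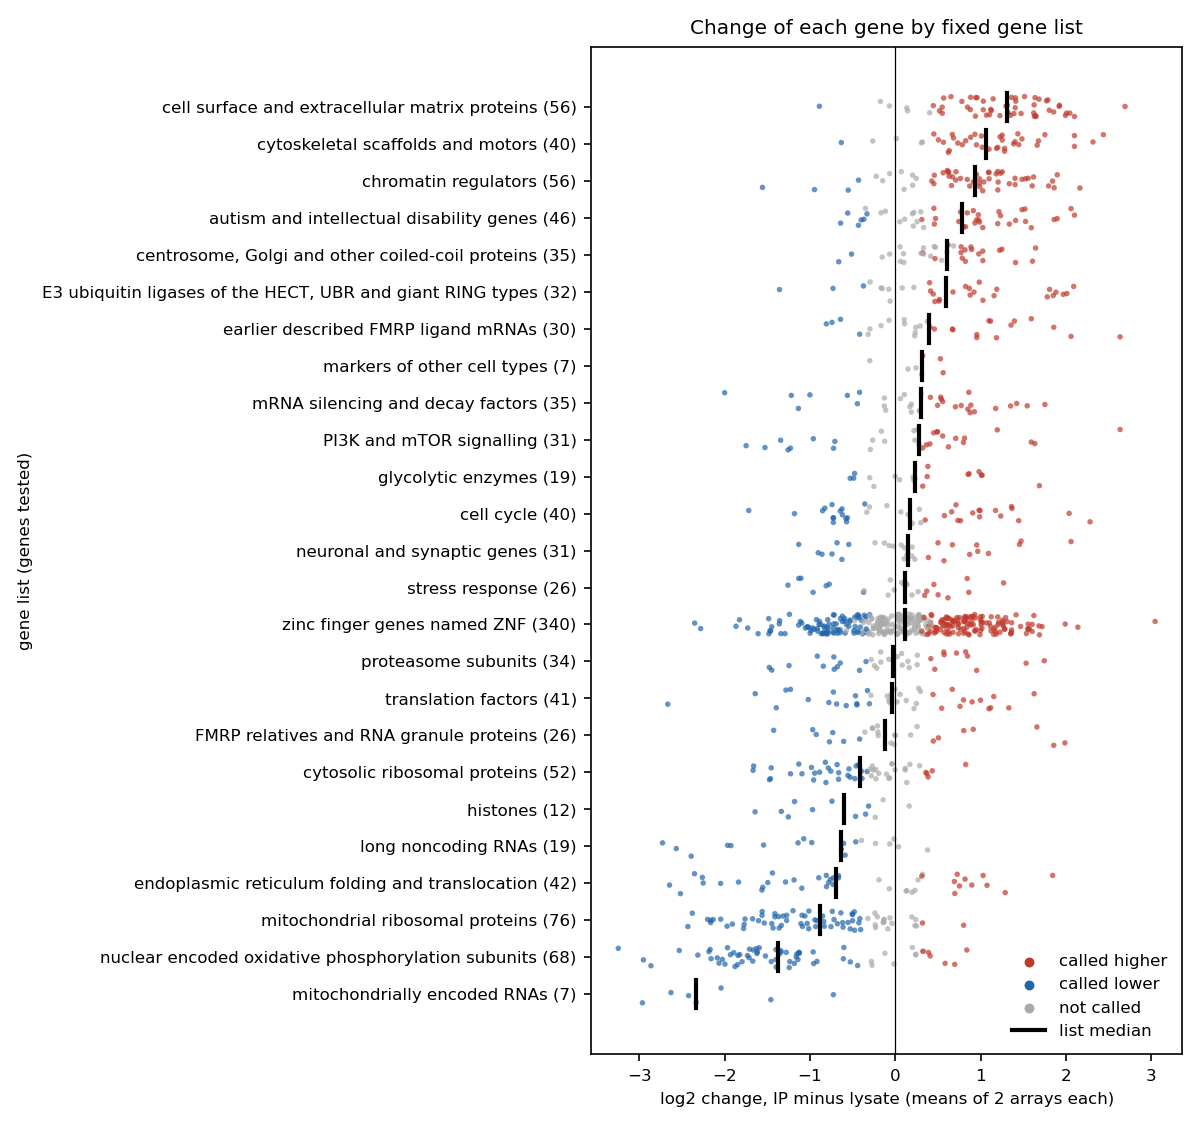
Log2 change, IP minus lysate (horizontal axis, means of 2 arrays each), of every tested gene of the 25 fixed gene lists (vertical axis, number tested in brackets); red points were called higher, blue lower and grey not called, and black bars are list medians. The medians run from -2.33 for mitochondrially encoded RNAs to 1.31 for cell surface and matrix genes; with hybridization control centring the same medians are -2.87 and 0.78.

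Genes of the mitochondrial gene expression and respiratory machinery were lower in the IP. Of 68 nuclear genes for oxidative phosphorylation subunits, 54 were lower and 6 higher, or 54 and 7 adjusted over the list alone, with a median of -1.38 (camera adjusted p = 5.4e-12; adjusted p = 0.296 with an estimated correlation). NDUFA1 and COX8A led the falls, and SDHA, the flavoprotein subunit of complex II, was higher at 0.84; without lysate replicate 1, 3 were higher. Of 76 genes for mitochondrial ribosomal proteins, 58 were lower and 2 higher, also adjusted over the list alone, with a median of -0.88 (camera adjusted p = 5.7e-12; adjusted p = 0.257 with an estimated correlation). MRPL32 and MRPL57 changed by -2.43 and -2.38, with other MRPL57 probe sets from -2.10 to -0.40, and MRPS15 (0.80) and DAP3 (0.32, named after its value was seen) were the higher genes; with any of the 4 arrays left out, 1 was higher. All 7 measured RNAs encoded by the mitochondrial genome were lower, also adjusted over the list alone, with a median of -2.33 (camera adjusted p = 0.00106; adjusted p = 0.544 with an estimated correlation). Their median was -1.71 on IP replicate 1 and -2.64 on IP replicate 2, each against the lysate mean; ATP6 changed by -2.96 and COX3 by -2.63. The medians of these 3 lists were -1.91, -1.42 and -2.87 with hybridization control centring. There 58, 70 and 7 genes were lower, none was higher, and SDHA (0.31) and MRPS15 (0.27) did not pass. The probe sets of SDHA and COX3 can cross-hybridize, and no other probe set of these genes was kept.

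Several other gene groups were lower on balance. Of 52 cytosolic ribosomal protein genes, 29 were lower and 5 higher, also adjusted over the list alone, with a median of -0.41 (camera adjusted p = 1.7e-04; adjusted p = 0.383 with an estimated correlation); RPS21 changed by -1.67, RPS29 by -1.66 and RPL3 by 0.83. The RPL3 probe set can cross-hybridize, and no other probe set of RPL3 was kept. The other higher genes, named after their values were seen, were RPL6, RPL19, RPL14 and RPS6, with changes of 0.43, 0.39, 0.37 and 0.36. The higher genes numbered 2 without lysate replicate 1, and 1 without lysate replicate 2 or without IP replicate 2, and the median of the 22 with unique probe sets was -0.69. Of 42 genes for endoplasmic reticulum folding and translocation, 23 were lower and 11 higher, or 23 and 12 adjusted over the list alone, with a median of -0.70 (camera adjusted p = 0.0223; adjusted p = 0.639 with an estimated correlation). DAD1 and SSR4, subunits of the oligosaccharyltransferase and of the translocon-associated complex, changed by -2.65 and -2.52, while the chaperone gene HSP90B1 rose 3.59-fold. The HSP90B1 probe set can cross-hybridize. Among the 23 of these genes whose 2 or more probe sets share a sign, an alternative chosen after seeing the data, 8 were higher and 11 lower, with a median of -0.19. Of 12 histone genes, 9 were lower and none higher, also adjusted over the list alone, with a median of -0.60 (camera adjusted p = 0.00296; adjusted p = 0.326 with an estimated correlation); the camera call was lost with unique probe sets, at a median of -0.66. H2BC21 changed by -1.64 and H2AZ2 by -1.34, and MACROH2A1 stood at 0.16 (adjusted p = 0.247), with other probe sets between -1.40 and 0.58. Of 19 long noncoding RNAs, 13 were lower and none higher, or 14 and 1 adjusted over the list alone, with a median of -0.63 (camera adjusted p = 2.1e-04; adjusted p = 0.383 with an estimated correlation). FTX fell from a lysate mean of 6.24 to an IP mean of 3.51 at the low end of the arrays, OIP5-AS1 changed by -2.57, and GAS5, at 4.54 and 4.92, had an adjusted p of 0.0586 over all genes. The noncoding median was -1.08 with the mean of each gene's probe sets and -0.98 in the 7 whose 2 or more probe sets share a sign, and GAS5 was called higher without lysate replicate 2. These 4 medians were -0.94, -1.23, -1.14 and -1.16 with hybridization control centring, where 42, 25, 11 and 18 genes were lower, 4 endoplasmic reticulum genes and none of the others were higher, and RPL3 (0.30) did not pass.

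Camera called none of the remaining 11 lists, and all but the markers of other cell types held members called in both directions. Of 26 genes for FMRP relatives and RNA granule proteins, 7 were higher and 7 lower (median -0.12, mean 0.05, camera direction down, adjusted p = 0.617); NUFIP2, encoding an FMRP-interacting protein, changed by -1.43 and TIA1 by -0.97. Among the 14 with unique probe sets 6 were higher and 3 lower, and the median turned to 0.12; without IP replicate 2 it was -0.05. Of 31 PI3K and mTOR signalling genes, 15 were higher and 8 lower (median 0.28, adjusted p = 0.608); among the 9 whose 2 or more probe sets share a sign, an alternative chosen after seeing the data, 1 was higher and 6 lower (median -0.72). With unique probe sets the PI3K median was 0.11. PIK3R4 changed by 1.64 and the Ragulator gene LAMTOR3 by -1.75. Of 35 silencing and decay factor genes, 17 were higher and 7 lower (median 0.30, adjusted p = 0.112): the decapping scaffold gene EDC4 rose 3.37-fold and the deadenylase gene PAN2 2.92-fold, while the deadenylase gene CNOT7 fell by 2.00; with unique probe sets the median was 0.17. Of 41 translation factor genes, 12 were higher and 15 lower (median -0.04, adjusted p = 0.63); the cap-binding protein gene EIF4E changed by -2.67, EIF5A by -1.64, and EIF3B by 1.63, with other EIF3B probe sets between -1.09 and 2.08. Of 34 proteasome genes, 10 were higher and 11 lower (median -0.03, adjusted p = 0.608), with PSMD2 at 1.75, PSME3 at -1.48 and PSMB3 at -1.45; the median was -0.15 with unique probe sets and -0.11 without lysate replicate 2. The translation factor median turned to 0.004 without lysate replicate 1 and to 0.009 without IP replicate 1. With hybridization control centring the counts were 3 higher and 17 lower for FMRP relatives and granule proteins, 5 and 24 for translation factors and 2 and 18 for the proteasome.

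Of 40 cell cycle genes, 17 were higher and 15 lower, or 18 and 17 adjusted over the list alone (median 0.18, adjusted p = 0.748); MKI67 and TOP2A rose 4.87-fold and 4.11-fold, and UBE2C changed by -1.72. The cell cycle median was 0.03 with unique probe sets and -0.30 in the 21 genes whose 2 or more probe sets share a sign. Of 19 glycolytic genes, 9 were higher and 3 lower (median 0.23, adjusted p = 0.251), with HK2 at 1.69, PFKL at 1.02 and TPI1 at -0.53, whose other probe sets changed by -0.50 and 0.12; the glycolytic median was 0.36 with unique probe sets. Of 26 stress response genes, 8 were higher and 7 lower (median 0.11, mean -0.03, camera direction down, adjusted p = 0.851); HSPH1 changed by 1.27, ASNS by 0.86 and EGR1 by -1.26. The stress median was -0.01 without lysate replicate 1, 0.04 without IP replicate 2 and 0.19 without lysate replicate 2. Of 31 neuronal and synaptic genes, 11 were higher and 7 lower (median 0.15, adjusted p = 0.518), with NCAM1 at 1.48 and VAMP2 at -1.13; the median was 0.09 without lysate replicate 2, 0.07 without IP replicate 2 and 0.31 in the 18 whose 2 or more probe sets share a sign. Of 340 ZNF genes, 129 were higher and 87 lower (median 0.11, adjusted p = 0.529), from ZNF91 at 3.05 to ZNF280B at -2.35, with other ZNF280B probe sets at -0.09 and -1.71; ZNF124 rose from a lysate mean of 3.81, low on the arrays, to an IP mean of 5.95. The ZNF median was 0.22 in the 107 whose 2 or more probe sets share a sign. Of 7 markers of other cell types, 3 were higher, 2 adjusted over the list alone, and none lower (median 0.31, adjusted p = 0.434): TTR (0.56), PECAM1 (0.53) and COL1A1 (0.32, named after its value was seen), and VWF stood at 4.97 and 4.67 (adjusted p = 0.0924). The median of the 7 markers was 0.16 without lysate replicate 2. None of these markers was called without lysate replicate 2 (TTR 0.45, PECAM1 0.41), PECAM1 did not pass without IP replicate 2 (0.37), where 1 marker was higher, and VWF was called lower without IP replicate 1. With hybridization control centring the medians of the PI3K, silencing, cell cycle, glycolytic, stress, neuronal, ZNF and other cell type lists all turned negative, from -0.22 to -0.42, with 4 higher and 12 lower, 5 and 10, 7 and 18, 3 and 7, 1 and 11, 4 and 11, 48 and 162, and 0 and 1; ASNS (0.33) and TTR (0.03) did not pass. Except where given, the counts adjusted over the list alone were the same.

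The median change differed little between 5 equal groups of genes by mean level over the 4 arrays, from 0.05 in the dimmest group to 0.12 in the next to brightest and 0.08 in the brightest. Grouped by lysate level, which is itself part of the change, the medians were 0.15, 0.18, 0.20, 0.03 and -0.32 from the dimmest to the brightest group. The 2632 dimmest genes had 754 higher and 246 lower, and the 2632 brightest 674 and 1312.

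Control transcripts with probe sets at both ends differed between the groups. For ACTB the signal at the 3' end exceeded that at the 5' end by 1.36 ± 0.02 in the lysate and 2.99 ± 0.04 in the IP (log2, mean ± SD, n = 2 each), and for GAPDH by 0.19 ± 0.00 and 0.98 ± 0.06. The spiked bacterial transcripts dap and thr gave 1.66 ± 0.07 and 2.04 ± 0.05 in the lysate and 2.24 ± 0.27 and 3.12 ± 0.16 in the IP, while phe and lys differed by 0.14 and 0.08 between groups. Every list described above was compared between arrays that differed in this way. An exact permutation test of 2 arrays against 2 cannot give a two-sided p under 0.333, so none is given.

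**Figure D3:**
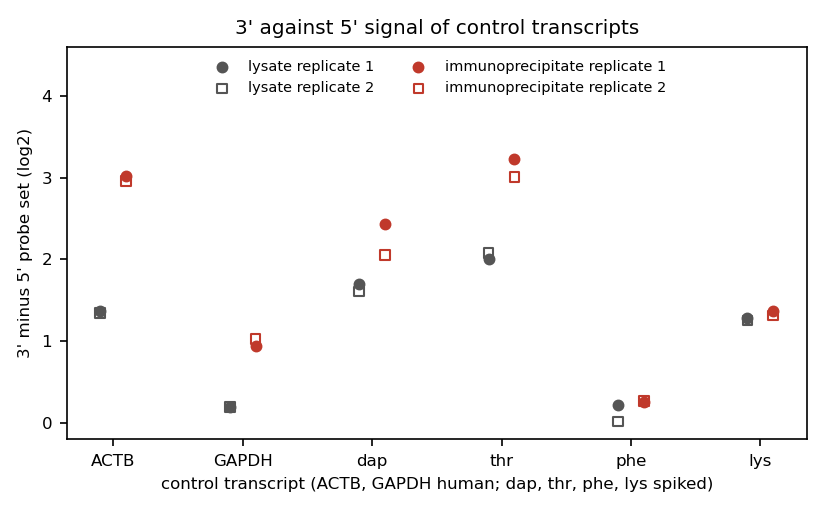
Difference of log2 signal between the 3' and 5' probe sets (vertical axis) of human ACTB and GAPDH and of 4 spiked bacterial control transcripts, per array; grey marks are lysate and red marks IP, circles replicate 1 and squares replicate 2. The ACTB difference is 1.34 to 1.37 on the lysate arrays and 2.96 to 3.02 on the IP arrays.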

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

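The patterns below were themselves picked from the results above. Of the tests in this part, the one that sets the risen genes against the hybridization controls, the one on small proteins and the one on cross-hybridization were chosen after the results were seen.

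Probe sets outside the gene-level comparison also carried signal: of 2641 kept probe sets without a gene symbol, 544 were higher and 675 lower in the IP, and 171 were at least 2-fold higher. The shares higher and lower are smaller than among all 27281 kept probe sets, where 8597 were higher and 7626 lower. Among the 13157 genes tested 4611 were higher, 3790 lower and 1639 at least 2-fold higher. Those genes are each represented by the brightest probe set, which is another unit. Of 1124 kept probe sets with several symbols, 332 were higher, 361 lower and 116 at least 2-fold higher. No explanation was tested for them.

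The first pattern is the rise of cell surface, cytoskeletal and chromatin mRNAs, 152 genes with a median change of 1.08. Random lists matched on mean level had a middle median of 0.072, and 0 of 10000 lay as far. This argues against mean signal level as the cause, but no lists were matched on lysate level. Shorter labelled products on the IP arrays may contribute and cannot be told apart from recovery with FMRP. The members lay 0.60 above the median change of the hybridization controls (0.48), less than the 1.63 by which the ACTB 3' to 5' difference grew. That growth came from the ACTB 5' probe set (-1.78), while its 3' probe set changed by -0.15, and GAPDH gave -1.11 and -0.31. It therefore does not measure a lift of 3' signal, and the comparison cannot decide. Transcript length was not analysed for these genes. Binding to FMRP stays a hypothesis, since no mock IP was measured.

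The second pattern is the fall of 144 mitochondrial ribosomal and oxidative phosphorylation mRNAs, with a median of -1.13. Random lists matched on mean level had a middle median of 0.11, and 0 of 10000 lay as low. These lists too were picked from the results, so this share does not measure chance. The middle median argues against mean signal level as the cause. No lists were matched on lysate level, by which the brightest of 5 groups of genes had a median of -0.32. An effect of lysate level therefore stays open. A set of 41 LSM, SNRP, PSMA and PSMB genes had a median of -0.53, higher by 0.61 (95% interval 0.24 to 0.93), but LSM genes alone had -0.93 and SMIM genes, for small integral membrane proteins, -0.91, so small size of the encoded protein may contribute and stays open, its length not being measured. Shorter labelled products stay open. The intraclass correlation of probe sets of the same member was 0.60 (95% interval 0.41 to 0.73). This lies between the values set in advance for either outcome. Over all 6246 genes with several kept probe sets the correlation was 0.71 (95% interval 0.70 to 0.73), a value inside the members' interval. The members' correlation therefore cannot be told apart from that of genes in general, and this test cannot decide. A lower recovery of these mRNAs with FMRP stays an open hypothesis.

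The third pattern is probe sets of the same gene called in opposite directions, 496 of 7622 called pairs (6.51%) in 298 genes. Pairs with opposite calls held 1 probe set of the class that can cross-hybridize with unrelated sequences (_x), against none, less often than pairs with the same call. The counts were 60 with it and 422 without, against 1111 and 5734 (odds ratio 0.73, 95% interval 0.52 to 0.98 with genes resampled). This argues against this class as the main cause. A planned test had pooled it with other probe sets. It was set aside after values were seen, and its result is not given here. Low signal may contribute and stays open, since the dimmer probe set of opposite pairs had a median level lower by 0.94 (change -0.94, 95% interval -1.13 to -0.79). Distance of the probe sets from the 3' end was not analysed here, and no biological explanation was tested.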

How the results depend on the processing

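The alternatives with genes whose probe sets share a sign and those of the 3' to 5' controls were chosen after seeing the data. The cause was not tested unless given. Called genes numbered 8401 and from 7395 to 8074 with each array left out, the lone array assumed to vary like the other group. Counts moved by over 1.5 times with all kept probe sets, which are more units (16223; 8597 higher, 7626 lower), with a change of at least 1 (3322; 1639 and 1683), with a minimum change of 0.5 in treat (4328; 2265 and 2063), in genes whose 2 or more probe sets share a sign, which are fewer (3463; 1922 and 1541), and with hybridization control centring in direction (1634 higher, 6442 lower). With the replicate number as a block, 8598 genes were called; deviations of same-numbered arrays correlated at 0.10 over only 2 pairs, so the pairing is not established, and the block changed no list call. With an estimated correlation all 14 camera calls were lost (4 lists at an unadjusted p under 0.05; fry called 19), at unchanged medians: ligands 0.39, autism genes 0.78, E3 ligases 0.60, chromatin 0.93, cytoskeleton 1.06, coiled-coil 0.61, cytosolic ribosome -0.41, mitochondrial ribosome -0.88, oxidative phosphorylation -1.38, endoplasmic reticulum -0.70, cell surface 1.31, histones -0.60, long noncoding RNAs -0.63 and mitochondrially encoded RNAs -2.33. With fry the coiled-coil call was lost (0.61), and 6 lists passed: PI3K 0.28, silencing 0.30, cell cycle 0.18, glycolysis 0.23, neuronal 0.15 and ZNF 0.11. Fry asks whether members change at all, camera whether they change more than other genes. With 63.9% of genes called and a median of 0.08 over all genes, passing fry does not set these lists apart from other genes. ZNF genes also passed with the stricter filter on level (0.28), and histones lost the call with unique probe sets (-0.66). Named genes that turned were TLN1 (-0.67), EIF3B (-1.09) and TPI1 (0.12) with unique probe sets, by construction another probe set, and PECAM1 (-0.003) with hybridization control centring. Named calls were lost with hybridization control centring (RPL3, MRPS15, SDHA, ASNS and TTR), with no filter (FMR1, EEA1 and PECAM1), and without lysate replicate 1 (FMR1 and EEA1), lysate replicate 2 (FMR1, GRM5, TTR and PECAM1) or IP replicate 2 (FMR1, EEA1 and PECAM1). With quantile normalization the ACTB 3' to 5' change was 1.77 in place of 1.63. Without renormalization, sorting genes by the lysate level in place of the mean level put the median of the brightest of 5 groups at -0.32 in place of 0.08. Pseudocounts do not apply to log2 values, and length groups were not run. Without detection calls, low signal limits the dim genes to an unknown extent.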

Other observations

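All tests in this part, of gene families by symbol stem and of gene classes, were chosen after the data were seen. Of 125 families with at least 12 tested genes, 11 were higher and 15 lower by camera, and none passed with an estimated correlation in camera (2 at an unadjusted p under 0.05; adjusted p = 0.643 or more for each of the families described here). DEAH-box helicase genes (DHX) were higher in 15 of 16, with a median of 1.09 and DHX9 at 2.37. Integrator subunit genes (INTS) were higher in 12 of 17 and lower in 2, with a median of 0.79 and INTS3 at 1.89. Both medians stayed above 0 with hybridization control centring, at 0.56 and 0.26.

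Other families were lower. Mitochondrial translocase genes (TIMM) were lower in 11 of 14, with a median of -0.96 and TIMM8B at -2.40. Small integral membrane protein genes (SMIM) were lower in 13 of 18 and higher in 2, with a median of -0.91 and SMIM30 at -2.36. RAB genes, which encode small GTPases of vesicle traffic, were lower in 30 of 57 and higher in 9, with a median of -0.38 and RAB8B at -2.39. NUDT hydrolase genes were lower in 11 of 19 and none was higher, with a median of -0.50 and NUDT21, encoding a cleavage factor subunit, at -1.60. By gene class, 34.7% of 646 noncoding RNA genes were lower and 13.0% higher, against 28.5% and 36.4% of 12286 protein-coding genes; the noncoding genes had a lower mean lysate level (5.96 against 7.81).

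The array's 18S ribosomal RNA probe sets differed by -2.27, -1.91 and -1.76 between IP and lysate, and its 28S probe sets by -2.44, -0.79 and -0.23, the last with overlapping groups. No test was run on them.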
